A study of Mus musculus with 6 samples.

How the data were processed

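The series holds 6 ribosome profiling libraries of MIN6 cells, 3 of cells with the sgNT guide and 3 of cells with the sgLTN1 guide. Per the labels' protocols, cell lysates were digested with RNase I, ribosomes were collected through a sucrose cushion, and the protected fragments were released, ligated to a linker, reverse transcribed, circularised and amplified by PCR. Groups were taken from the genotype in the labels and library numbers from the titles. All 6 libraries share a single batch label, so no batch could be compared.

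The authors deposited a table of whole-number read counts per gene, with one column per library and with Ensembl identifiers paired with symbols. Per the submitters' processing notes, fastp 0.23.4, UMI-tools 1.1.2, Bowtie2 2.5.4, STAR 2.7.11a, SAMtools 1.9 and featureCounts 2.12.3 were used with the mouse build GRCm39. The notes as used here give no roles or settings: the gene annotation, the strand setting, the handling of reads with several alignments, the use of unique molecular identifiers and any selection by footprint length or reading frame are not given in the sources used here. Genes with many near-identical copies can lose reads in such counting. Overlapping and antisense genes cannot be told apart where strand was not used. A second table deposited by the authors holds, per the file headers, results of DESeq2 (1.38.3 in the notes): the log2 fold change and its standard error, the mean normalized count as a signal level, the Wald statistic as a score, and the p-value with its adjusted form. The direction of that table was checked against the counts, and DESeq2 run here on the deposited counts gave the same 227 calls.

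The count table lists 21652 genes, of which 798 had no count in any library and 23 repeat a symbol. A RefSeq gene table of assembly GRCm38 was used only for gene class and for which genes neighbour each other. It matched 19597 genes, 19385 of them protein coding, and 54 tested genes were of another class. Since the builds differ, no coordinates are given. All columns of sample values were used.

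Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept by filterByExpr with default settings, which left 12782. Libraries were scaled by TMM (factors 0.954 to 1.04), and CPM values are counts scaled to a common library size by the cpm function. The test was edgeR's quasi-likelihood test of sgLTN1 against sgNT over all 6 libraries with group as the only term, and adjusted p-values are Benjamini-Hochberg values over the tested genes with a threshold of 0.05. The biological coefficient of variation was 8.92%. Log2 fold changes are sgLTN1 over sgNT, with a standard error from the test statistic. A prior count of 2 was used for log CPM values. Where a group held 0 counts, the fold is a lower bound against a floor of 3 counts over the group's total, and with 1 count the ratio has an exact 95% interval. Reads may not be independent molecules, so these intervals and floors cover counting error only.

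The comparison, its test, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule names Ltn1, Rnf10, Ins1 and Ins2; then up to 12 genes with the largest rise and 12 with the largest fall among protein-coding genes past the threshold with a mean of at least 10 CPM in the higher group and no overlap between groups, which gave 11 and 8 genes; then the 4 members with the smallest p in each list that holds a gene past the threshold, and the 2 with the smallest p in other lists. Some genes that the rule names are left out of the text, and the counts of genes include them. The 29 lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry. Lists share some members. Each list's median was also set among 10000 random lists of equal size matched on abundance. Shares of counts were compared with a two-sided exact permutation test over the 20 labellings of the 6 libraries.

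Replicate libraries were compared before they were averaged. Every pair differed by more than sampling noise, with a chi-square per degree of freedom of 2.42 for the closest pair, sgLTN1 libraries 1 and 2, so each library was counted as a sample. Depth differed between libraries, from 4373467 to 11198735 counts, and genes of low count are measured less precisely in sgNT libraries 1 and 3 and sgLTN1 library 3.

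The gene and list tests were first tested on simulated data made from the libraries' own means and totals for sgLTN1 against sgNT, with 200 genes altered by fixed folds and 1 list shifted by 0.2. With dispersions drawn per gene over 12632 genes, the test recovered 8.16% of genes altered 1.3-fold, 37.5% at 1.5-fold, 73.5% at 2-fold and 93.8% at 3-fold, and 19 of 123 calls were unaltered genes. With dispersions on the trend over 12608 genes, it recovered 24%, 32.7%, 91.8% and 97.9%, and 6 of 126 calls were unaltered genes. At this depth and number of libraries, a change of 1.3-fold was therefore mostly not detectable for a single gene. In both simulations, the shifted list was the only one of 29 called. The simulated genes were drawn independently and without an abundance trend. In the data the estimated inter-gene correlation was 0.48 for the ER unfolded protein response list and 0.87 for the mitochondrially encoded list. The simulation therefore does not show how the list test behaves with correlated genes.

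The alternatives were DESeq2 1.42.0, limma-voom, DESeq2 size factors, upper-quartile factors and total counts in place of TMM, other filters on low counts, leaving out genes above 1% of a library, the replicate number as a block, leaving out each library, protein-coding genes only, other thresholds and a test against a fold of 1.2. Alternatives for normalized values were not needed, as the values are counts. Thinning all libraries to the smallest total of 4373467 counts (1 draw) and removing each library's loess trend over abundance (span 0.3), the latter also with an estimated correlation in camera, were added after the data were seen. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.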

Results

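Ribosome profiling sequences the short mRNA fragments that ribosomes protect from nuclease digestion, so that the number of footprints on a gene reflects both the amount of its mRNA and how densely that mRNA is occupied by ribosomes. Footprints were measured in MIN6 cells, a mouse insulin-secreting line derived from a pancreatic beta-cell tumour. The cells expressed either sgNT, taken here as the non-targeting control guide, or sgLTN1, a CRISPR guide against Ltn1, with 3 libraries in each group. The gene totals were 4373467, 7802364 and 4479680 counts in sgNT libraries 1 to 3 and 11198735, 9683201 and 4993245 counts in sgLTN1 libraries 1 to 3. Of 21652 listed genes, 12782 had enough counts to be tested. The labels do not say whether the libraries of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical. RNA-seq of the same cells was not used here, so a change in footprints was not divided into mRNA level and translation.

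The comparison of sgLTN1 with sgNT asks how targeting Ltn1 alters ribosome occupancy, and the title of the series directs attention to Rnf10. Ltn1 encodes Listerin, the E3 ubiquitin ligase of ribosome-associated quality control that marks incomplete nascent chains on stalled 60S subunits. Footprints on Ltn1 (ENSMUSG00000052299.10) fell from 143 ± 1.84 to 67.2 ± 3.67 CPM (library-scaled counts; mean ± SD, n = 3 per group), which left 0.470 of the control level. The 3 control libraries read 143, 145 and 141 CPM and the 3 sgLTN1 libraries 65.3, 71.4 and 64.9 CPM, so the guide named in the labels went with lower footprints on its target in each library. The log2 fold change was -1.09 (SE 0.07), with adjusted p = 9.24e-05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and Ltn1 had the smallest adjusted p of the 12782 tested genes. The authors' deposited table gave a log2 fold change of -1.07 (SE 0.10) with adjusted p = 5.53e-23.

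Rnf10 encodes the E3 ligase that ubiquitinates uS3, the product of Rps3, on the 40S subunit. Footprints on Rnf10 (ENSMUSG00000041740.17) were 39.1 ± 4.93 CPM in sgNT and 31.1 ± 2.51 CPM in sgLTN1, a log2 fold change of -0.34 (SE 0.11). The values of the groups did not overlap, but the difference did not pass the threshold over all genes (adjusted p = 0.177) nor over its list of 40S ubiquitination genes alone. The authors' deposited table gave -0.32 (SE 0.15) with an unadjusted p = 0.0314 and no adjusted p. Rps3 itself, a gene outside the naming rule, read 211 ± 10.3 and 213 ± 7.86 CPM, with a log2 fold change of 0.01 (SE 0.06) and adjusted p = 0.966. Footprints measure neither the level of the RNF10 protein nor uS3 ubiquitination.

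Across all genes, 23 passed an adjusted p of 0.05, 11 higher and 12 lower in sgLTN1. The rises were between 0.34 and 0.86 on the log2 scale. Several of the genes encode secreted proteins. Footprints on Adm, the precursor of the vasodilator peptide adrenomedullin, rose from 19.5 ± 1.66 to 29.9 ± 2.33 CPM (0.64, SE 0.10, adjusted p = 0.0391). Agt, which encodes angiotensinogen, rose from 622 ± 14.5 to 847 ± 38.6 CPM (0.45, SE 0.06, adjusted p = 0.0119). Gc, the vitamin D-binding protein, rose from 404 ± 22.2 to 556 ± 28.9 CPM (0.46, SE 0.06), Ttr, the thyroid hormone carrier transthyretin, from 3641 ± 109 to 4706 ± 334 CPM (0.37, SE 0.06), and Lama5, a laminin chain of basement membranes, from 214 ± 5.41 to 275 ± 2.04 CPM (0.36, SE 0.06). Membrane proteins were represented by Slc35d3 (0.86, SE 0.12, from 9.68 ± 0.436 to 17.5 ± 1.56 CPM), Slc22a23 (0.54, SE 0.08) and Dlk1, an imprinted transmembrane protein with EGF-like repeats, which rose from 3864 ± 236 to 5163 ± 231 CPM (0.42, SE 0.06). Rises were also seen in Ggcx (0.34, SE 0.05), the vitamin K-dependent carboxylase of the endoplasmic reticulum (ER), and Bcl9 (0.60, SE 0.10), a coactivator of beta-catenin.

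Among the falls, Gpnmb, which encodes a transmembrane glycoprotein, went from 17.8 ± 0.129 to 8.90 ± 1.09 CPM (-1.02, SE 0.13, adjusted p = 0.0119). Ass1, the argininosuccinate synthase that makes the precursor of arginine, went from 61.8 ± 1.65 to 32.4 ± 2.71 CPM (-0.94, SE 0.08, adjusted p = 0.0019). Penk, which encodes the opioid peptide precursor proenkephalin, went from 91.6 ± 9.54 to 54.7 ± 2.05 CPM (-0.74, SE 0.09, adjusted p = 0.00696), and the linker histone gene H1f1 from 108 ± 3.68 to 70.0 ± 3.89 CPM (-0.62, SE 0.07, adjusted p = 0.00696). Itgb3bp, a centromere protein gene, fell (-0.89, SE 0.14), as did Ntn1, which encodes the guidance cue netrin 1 (-0.77, SE 0.12), and Nr4a1, an immediate early nuclear receptor (-0.71, SE 0.12). H1f1 shares sequence with other linker histone genes, and its count is uncertain to that extent.

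Another 4 genes that fell lay under the 10 CPM minimum of the naming rule and were chosen after their values were seen. Il11, an interleukin gene, fell from 6.12 ± 0.614 to 1.76 ± 0.324 CPM (-1.80, SE 0.24, adjusted p = 0.015). The neighbouring and near-identical genes Dcpp1, Dcpp2 and Dcpp3, which encode secreted proteins known from salivary glands, held 58, 78 and 67 counts over the 3 sgNT libraries and 1, 0 and 0 over the 3 sgLTN1 libraries. Against a floor of 3 counts over the group, Dcpp2 was at least 40.4-fold lower and Dcpp3 at least 34.7-fold lower. For Dcpp1 the ratio of sgNT to sgLTN1 was 90.1, with a 95% exact interval of 15.5 to 3620 that covers counting error only. Reads of these 3 genes can be exchanged between them.

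**Figure D1:**
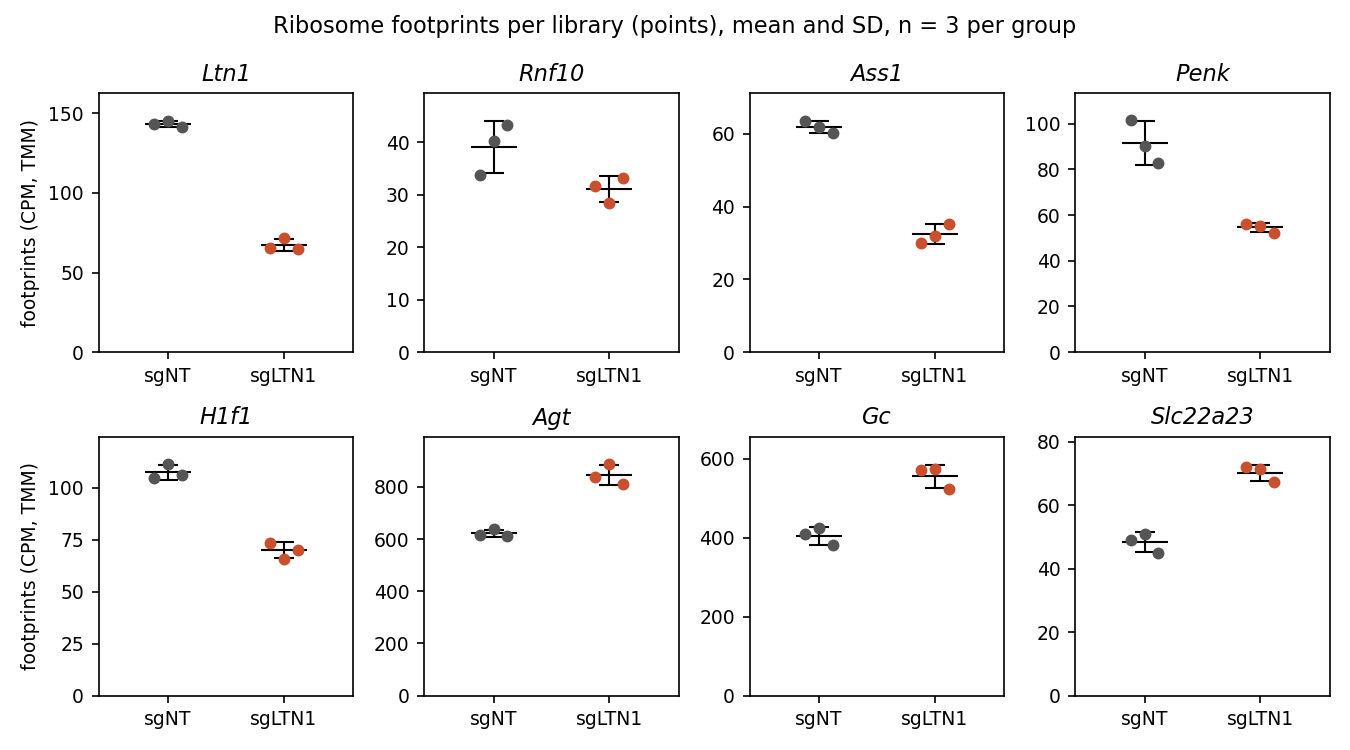
Footprints in CPM (vertical axis, from 0) for 8 genes in sgNT (grey) and sgLTN1 (orange), with points for the 3 libraries of each group and lines for the mean and SD. Ltn1 falls from 143 to 67.2 CPM with no overlap of the groups, Rnf10 differs by less (39.1 and 31.1 CPM), Ass1, Penk and H1f1 lie lower and Agt, Gc and Slc22a23 higher in sgLTN1.

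All 23 genes had values that did not overlap between the groups. Such separation was seen for 2576 of the tested genes (20.2%), where chance gives 10%, and 1989 genes (15.6%) had an unadjusted p below 0.05, 1023 of them higher and 966 lower. The calls depended on single libraries: leaving out one library at a time gave between 4 genes (without sgLTN1 library 2) and 333 genes (without sgLTN1 library 3), and no gene was called higher without sgNT library 1, sgNT library 2, sgLTN1 library 1 or sgLTN1 library 2. The authors' deposited table called 227 genes, 183 higher and 44 lower, and it gave an adjusted p only for 2697 genes with a mean normalized count of at least 309. Among these 2697 genes, called or not, 1794 were higher and 903 lower there. Of the 23 genes, 11 had an adjusted p in the authors' deposited table, and all 11 were called there. Scaling by total counts gave 8 genes higher and 34 lower.

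The hormones that define the line differed little. Ins2 read 47665 ± 2533 CPM in sgNT and 50415 ± 5934 CPM in sgLTN1 (0.08, SE 0.08, adjusted p = 0.681), and Ins1 12956 ± 437 and 14013 ± 1359 CPM (0.11, SE 0.07, adjusted p = 0.466), with both values turning negative once the trend described in the next paragraph was removed. Ins1 and Ins2 together took 6.20% ± 0.219 of the counts in sgNT and 6.25% ± 0.657 in sgLTN1 (two-sided exact permutation test, p = 1). The share of mitochondrially encoded genes was 0.812% ± 0.133 and 0.703% ± 0.0831 (exact permutation p = 0.3), that of ribosomal protein genes 0.542% ± 0.0328 and 0.521% ± 0.0241 (exact permutation p = 0.4), and that of the 10 most abundant genes 21.5% ± 0.821 and 21.6% ± 1.34 (exact permutation p = 1). With 3 libraries per group, the smallest p this test can give is 0.1.

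Fold changes moved with abundance. The median log2 fold change was -0.11 for the 2171 genes under 2 on the log2 CPM scale, -0.05 for the 4748 genes between 2 and 4, -0.00 for the 3825 genes between 4 and 6, 0.04 for the 1533 genes between 6 and 8 and 0.14 for the 505 most abundant genes, of which 81.4% were higher in sgLTN1. The distance between abundant and scarce genes was 0.09, 0.16 and -0.01 in sgLTN1 libraries 1 to 3 and -0.03, -0.07 and -0.17 in sgNT libraries 1 to 3, so sgLTN1 library 3 and sgNT library 1 lay close together. Each called list is therefore given with its median and with the median after this trend was removed, a setting added after the data were seen.

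**Figure D2:**
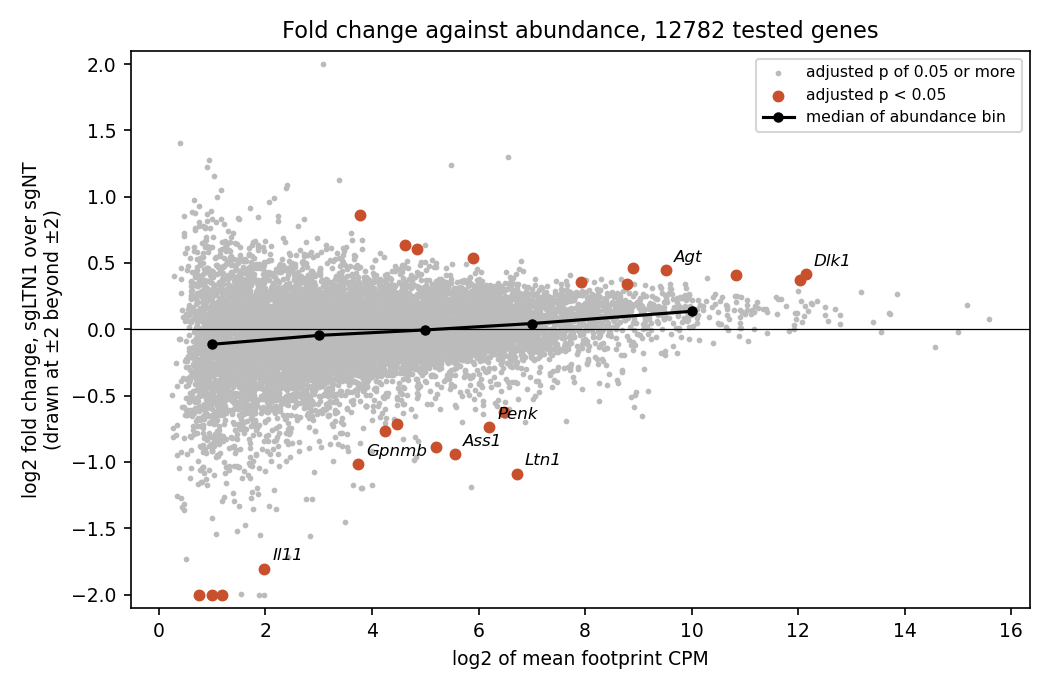
Log2 fold change of sgLTN1 over sgNT (vertical axis, values beyond 2 in size drawn at the edge) against the log2 of the mean CPM (horizontal axis) for the 12782 tested genes, with the 23 genes past an adjusted p of 0.05 in orange and the median of each abundance bin as a black line. The medians run from -0.11 in the scarcest bin to 0.14 in the most abundant one.

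Of 29 gene lists, 13 shifted against the other genes in camera with a preset inter-gene correlation of 0.01, 6 upward and 7 downward. With an estimated correlation no list was called, the lowest adjusted p being 0.422, and none was called with an estimated correlation once the abundance trend was removed (lowest adjusted p = 0.415). The one-way test of fry, which asks whether the members of a list move on balance in one direction, called 0 lists (lowest adjusted p = 0.105), and its test of change in either direction called 19. Among random lists matched on abundance, medians of the 7 lists called lower lay at percentiles 0 to 0.21. Beside the ER list below, those called higher lay at 48.9 (glycolysis), 60.7 (secretory granule), 69.0 (beta-cell), 71.1 (lysosome) and 94.95 (cholesterol). The lowest uncalled lists were integrated stress response targets (0.14) and nerve and synapse genes (0.27). Random lists do not keep the correlation between members.

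Genes of the ER unfolded protein response, which encode chaperones, translocon and ER-associated degradation proteins, were higher as a group. All 34 tested members had a log2 fold change above 0, with a median of 0.16 (camera adjusted p = 1.96e-12; adjusted p = 0.422 with an estimated correlation). No member passed over all genes, and 10 rose when adjusted over the list alone. Among them, the stress sensor kinase gene Ern1 read 176 ± 8.47 and 226 ± 3.34 CPM (0.36, SE 0.06), and the ER oxidase gene Ero1a 226 ± 14.4 and 292 ± 34.4 CPM (0.37, SE 0.09). The list's median lay at percentile 99.1 of 10000 random lists matched on abundance, whose median was 0.10. With the abundance trend removed, 27 of 34 members stayed above 0 with a median of 0.06 (camera adjusted p = 0.0011; adjusted p = 0.415 with an estimated correlation).

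Cholesterol synthesis genes were higher too, with 20 of 25 members above 0 and a median of 0.12 (camera adjusted p = 1.88e-04; adjusted p = 0.422 with an estimated correlation). None passed over all genes and 6 rose adjusted over the list alone. The median was 0.08 without the abundance trend (camera adjusted p = 0.00914; adjusted p = 0.461 with an estimated correlation) and 0.18 without sgNT library 2.

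The other 4 upward shifts ended when the abundance trend was removed. For glycolysis and hypoxia the median was 0.07, with 21 of 28 members above 0 (camera adjusted p = 1.05e-04; adjusted p = 0.422 with an estimated correlation). In this list Adm rose over all genes and 6 genes rose adjusted over the list alone, among them the collagen prolyl hydroxylase gene P4ha2 (0.31, SE 0.07) and the glucose transporter gene Slc2a1 (0.36, SE 0.08), while the members that perform glycolysis included Gapdh with only 7 to 11 counts per library. Without the trend the median was 0.00 (adjusted p = 0.0586), and it was 0.12 without sgNT library 1, 0.10 without sgNT library 2 and 0.10 without sgLTN1 library 1. Secretory granule and prohormone processing genes had a median of 0.11, with 22 of 30 members above 0 (camera adjusted p = 0.00296; adjusted p = 0.472 with an estimated correlation). Adjusted over the list alone 8 rose and 1 fell, with the granins Chgb (0.28, SE 0.06) and Scg2 (0.27, SE 0.06) in the lead and none past the threshold over all genes. The median turned to -0.03 without the trend (adjusted p = 0.463).

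Beta-cell identity genes had a median of 0.09, with 22 of 32 members above 0 (camera adjusted p = 0.0114; adjusted p = 0.422 with an estimated correlation). None passed over all genes, and adjusted over the list alone 6 rose and 1 fell, with Cltrn (0.27, SE 0.06) and the incretin receptor gene Glp1r (0.23, SE 0.07) at the smallest p. The median was 0.03 without the trend (adjusted p = 0.763), 0.13 without sgNT library 1 and 0.15 without sgLTN1 library 1. Lysosome and autophagy genes had a median of 0.11, with 22 of 35 members above 0 (camera adjusted p = 0.0207; adjusted p = 0.472 with an estimated correlation). None of them passed over all genes or adjusted over the list alone, Ctsa being at 0.18 (SE 0.05), and the median turned to -0.02 without the trend (adjusted p = 0.386). Without sgNT library 3 the calls of the secretory granule (adjusted p = 0.0586), beta-cell (adjusted p = 0.138) and lysosome lists (adjusted p = 0.147) ended, and without sgLTN1 library 2 that of the lysosome list (median 0.07, adjusted p = 0.117). The secretory granule call also ended when the 10 genes above 1% of a library were left out (adjusted p = 0.0526).

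**Figure D3:**
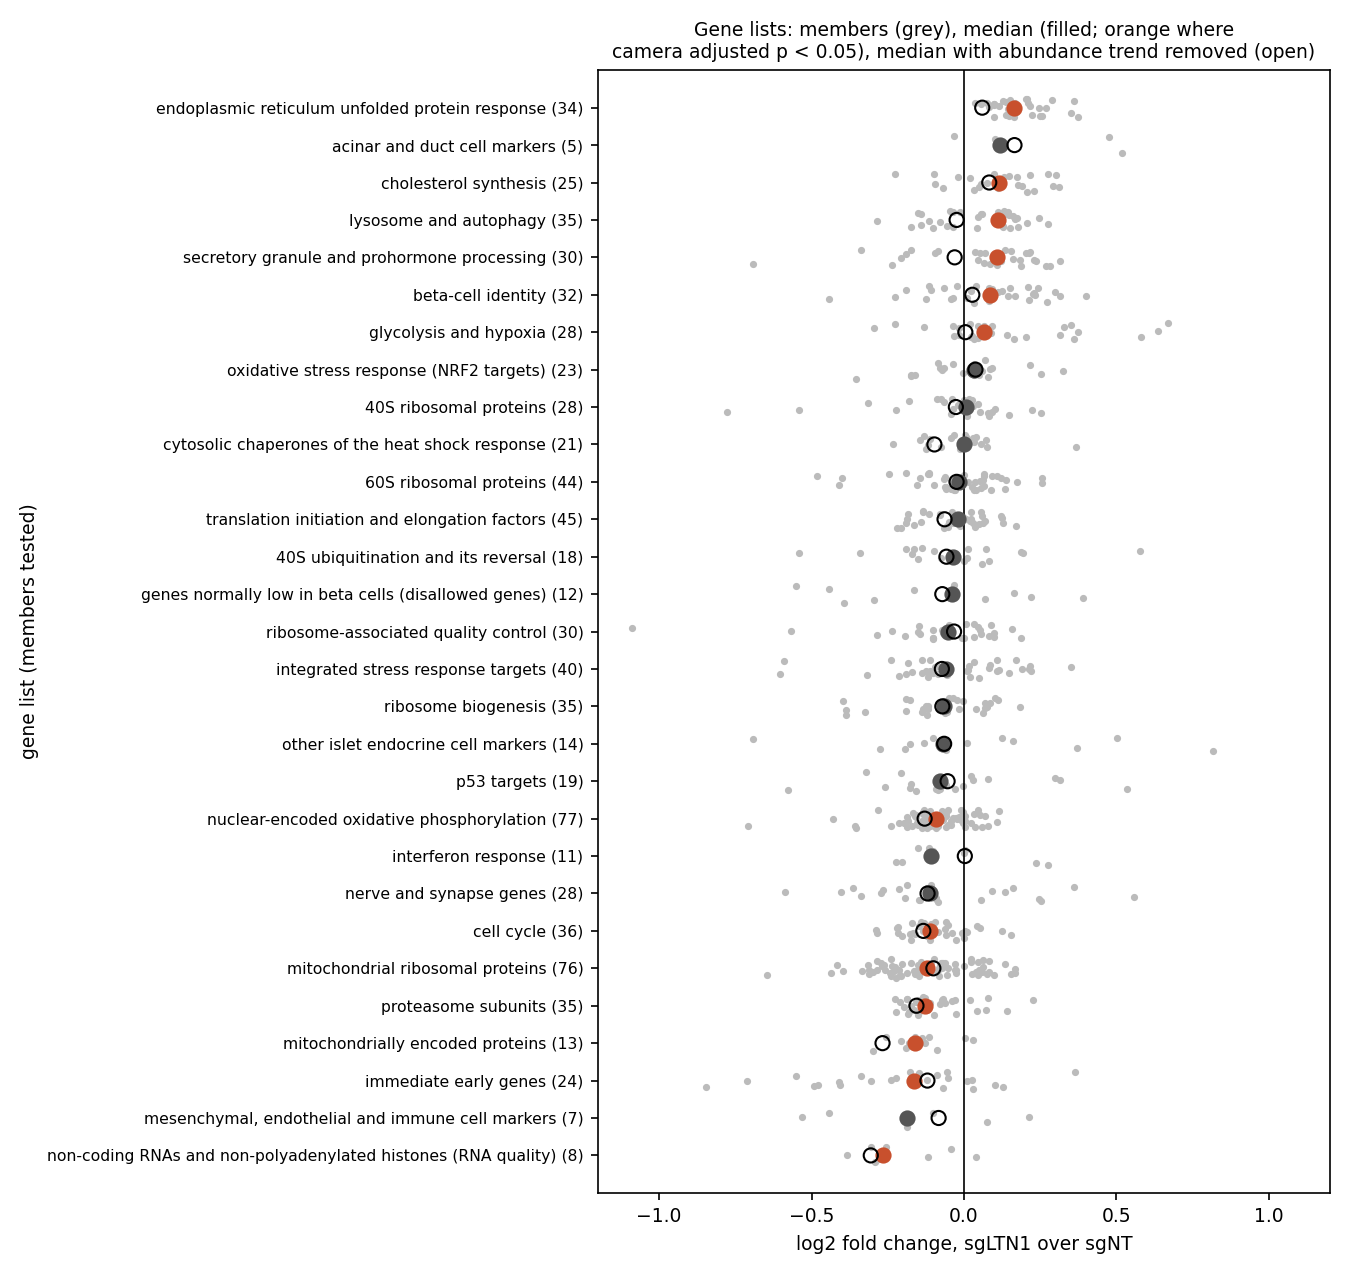
Log2 fold change of sgLTN1 over sgNT (horizontal axis) for the members of 29 gene lists (vertical axis, members tested in brackets), with grey points for members, filled points for list medians (orange where the camera adjusted p was below 0.05) and open circles for medians after the abundance trend was removed. ER unfolded protein response genes have the highest median among the called lists (0.16) and the histone-dominated list the lowest (-0.27), and the secretory granule and lysosome medians lie on the other side of 0 once the trend is removed.

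Histone genes were lower. In the list of non-coding RNAs and histones, set up to follow RNA quality, the 8 members with enough counts were histone genes, and 7 of them lay below 0 with a median of -0.27 (camera adjusted p = 1.05e-04; adjusted p = 0.422 with an estimated correlation). None passed over all genes and 5 fell adjusted over the list alone. These were the linker histone genes H1f4 (-0.38, SE 0.07, 438 ± 21.5 and 336 ± 21.5 CPM) and H1f2 (-0.30, SE 0.06) and, outside the naming rule and chosen after their values were seen, the core histone genes H4c4 (-0.29, SE 0.07), H2bc4 (-0.25, SE 0.08) and H3c2 (-0.28, SE 0.09). Without the abundance trend the median was -0.31 (adjusted p = 1.03e-05; adjusted p = 0.415 with an estimated correlation).

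Mitochondrial genes were lower in 3 lists. Nuclear-encoded oxidative phosphorylation genes had a median of -0.09, with 64 of 77 members below 0 (camera adjusted p = 0.00247; adjusted p = 0.472 with an estimated correlation), led by the complex I gene Ndufs3 (-0.28, SE 0.08) and the ATP synthase inhibitor gene Atp5if1 (-0.35, SE 0.10). Mitochondrial ribosomal protein genes had a median of -0.12, with 57 of 76 below 0 (camera adjusted p = 0.00296; adjusted p = 0.422 with an estimated correlation), led by Mrps25 (-0.65, SE 0.16) and Mrpl46 (-0.40, SE 0.13). The 13 mitochondrially encoded genes, with 11 below 0, had a median of -0.16 (camera adjusted p = 0.031; adjusted p = 0.702 with an estimated correlation), with mt-Nd4l at -0.30 (SE 0.14) and mt-Nd2 at -0.21 (SE 0.11). No member of these lists passed over all genes or adjusted over the list alone. Without the abundance trend the medians were -0.13 for oxidative phosphorylation (adjusted p = 4.64e-08), -0.10 for mitochondrial ribosomal proteins (adjusted p = 0.0127) and -0.27 for the mitochondrially encoded genes (adjusted p = 1.24e-04), with adjusted p = 0.461, 0.415 and 0.466 with an estimated correlation. The oxidative phosphorylation median was -0.05 without sgNT library 3 and -0.06 without sgLTN1 library 2, and the mitochondrial ribosomal median -0.07 without sgLTN1 library 2, with the calls kept. The mitochondrially encoded list was called in only 2 of the 6 fits that left out a library, with medians of -0.26 without sgNT library 2 and -0.24 without sgLTN1 library 1, and the call was lost without sgNT library 3 (-0.02), sgLTN1 library 2 (-0.09), sgNT library 1 (-0.15) and sgLTN1 library 3 (-0.12).

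Proteasome subunit genes had a median of -0.13, with 29 of 35 below 0 (camera adjusted p = 0.00296; adjusted p = 0.422 with an estimated correlation). Psmd6 read 120 ± 3.75 and 106 ± 2.18 CPM (-0.18, SE 0.06), whereas Nfe2l1, which encodes a transcription factor for proteasome genes, was at 0.23 (SE 0.08). Cell cycle genes had a median of -0.11, with 29 of 36 below 0 (camera adjusted p = 0.00296; adjusted p = 0.422 with an estimated correlation), led by the spindle gene Tpx2 (-0.22, SE 0.07) and Birc5 (-0.29, SE 0.10). In neither list did a member pass over all genes or adjusted over the list alone. Immediate early genes, which respond within minutes to stimulation, had a median of -0.16, with 18 of 24 below 0 (camera adjusted p = 0.0064; adjusted p = 0.422 with an estimated correlation). Nr4a1 fell over all genes, and Nr4a1 and Fosb (-0.85, SE 0.21, 10.3 ± 2.20 and 5.74 ± 1.16 CPM) fell adjusted over the list alone. Klf10 was at -0.41 (SE 0.16) and Egr1 at -0.49 (SE 0.19). The call of Nr4a1 over all genes held in 11 of 18 other settings, and was lost with the abundance trend removed. Without the abundance trend the medians were -0.16 for the proteasome (adjusted p = 4.08e-06), -0.13 for the cell cycle (adjusted p = 4.20e-07) and -0.12 for immediate early genes (adjusted p = 0.0217), with adjusted p = 0.415, 0.415 and 0.461 with an estimated correlation. The proteasome median was -0.07 without sgNT library 3, with the call kept, and the cell cycle call ended without sgNT library 2 (median -0.07, adjusted p = 0.0835) or sgLTN1 library 3 (median -0.09, adjusted p = 0.0947). The immediate early call ended without sgNT library 1 with the median unmoved at -0.16 (adjusted p = 0.0515), and without sgLTN1 library 1 with the median at -0.06 (adjusted p = 0.136).

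Genes of ribosome-associated quality control did not shift as a list (median -0.05, camera adjusted p = 0.0593). Of 30 members only Ltn1 fell, over all genes and adjusted over the list alone, and the other 29 did not pass. Nemf, whose product binds 60S subunits together with Listerin, read 81.0 ± 31.3 and 54.6 ± 13.2 CPM (-0.57, SE 0.25, adjusted p = 0.31), Ankzf1, which encodes the peptidyl-tRNA hydrolase of the pathway, 157 ± 20.5 and 129 ± 19.1 CPM (-0.29, SE 0.12), and Ascc2 22.6 ± 0.808 and 19.8 ± 1.40 CPM (-0.19, SE 0.10). The list passed the threshold without sgLTN1 library 3 (adjusted p = 0.0485). The genes of 40S ubiquitination and its reversal gave a median of -0.04 (camera adjusted p = 0.831), with 0 of 18 past the threshold and G3bp2 at -0.14 (SE 0.07).

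The translation machinery showed no called shift. The 28 tested genes of 40S ribosomal proteins had a median of 0.01 (camera adjusted p = 0.84), with Rps24 at 0.25 (SE 0.12) and Rps6 at -0.18 (SE 0.09), and the 44 of 60S proteins -0.02 (adjusted p = 0.91), with Rplp0 and Rplp1 both at 0.26 (SE 0.11 and 0.12). Many ribosomal protein genes have processed copies, which makes their counts uncertain. Translation factors gave a median of -0.02 (adjusted p = 0.573), with Eif3g at -0.22 (SE 0.08) and Eif3e at -0.19 (SE 0.07). Ribosome biogenesis genes gave -0.06 (adjusted p = 0.111), with Bms1 at -0.32 (SE 0.09) and Nob1 at -0.40 (SE 0.12). No member of these 4 lists passed over all genes or adjusted over the list alone.

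Targets of the integrated stress response went both ways (median -0.06, camera adjusted p = 0.774). None of 40 passed over all genes. Adjusted over the list alone 3 fell, the alanyl-tRNA synthetase gene Aars1 (-0.24, SE 0.06), Gpt2 (-0.32, SE 0.08) and Ppp1r15a (-0.60, SE 0.17), and 3 rose, the amino acid transporter genes Slc7a1 (0.21, SE 0.06) and Slc7a3 (0.22, SE 0.06) and Ddit4 (0.35, SE 0.09). The last 3 and Ppp1r15a were outside the naming rule and chosen after their values were seen. Cytosolic chaperone genes gave a median of 0.00 (adjusted p = 0.774), with Hsf1 at 0.37 (SE 0.17), Fkbp4 at -0.23 (SE 0.11) and none past either threshold. Once the abundance trend was removed, the lists of translation factors (-0.06, adjusted p = 0.00659), ribosome biogenesis (-0.07, adjusted p = 0.035), stress response targets (-0.07, adjusted p = 0.0252), cytosolic chaperones (-0.10, adjusted p = 0.0148) and nerve and synapse genes (-0.12, adjusted p = 0.0148) were called lower at the preset correlation. None of the 5 was called with an estimated correlation and the trend removed (adjusted p = 0.461, 0.461, 0.513, 0.415 and 0.415 in the same order).

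Markers of other cell types were mostly scarce. Of 23 acinar and duct markers 5 had enough counts (median 0.12, camera adjusted p = 0.0593), with Krt8 at 8.67 ± 0.965 and 12.3 ± 0.774 CPM, which rose adjusted over the list alone (0.48, SE 0.14), and Spp1 at 0.12 (SE 0.05). Of 20 mesenchymal, endothelial and immune markers 7 were tested (median -0.19, adjusted p = 0.325), with Vim at -0.53 (SE 0.26), Cd68 at -0.19 (SE 0.11) and none past either threshold. Among 14 tested markers of other islet cells the median was -0.07 (adjusted p = 0.275). Ttr rose over all genes, and adjusted over the list alone 3 rose and 1 fell, the rises being in Ttr, the somatostatin gene Sst (0.50, SE 0.09, 30.4 ± 1.42 and 43.3 ± 3.65 CPM) and Ppy (0.82, SE 0.26). Of 12 genes normally low in beta cells (median -0.04, adjusted p = 0.84), Igfbp4 fell (-0.44, SE 0.11) and Cxcl12 rose (0.39, SE 0.11) adjusted over the list alone.

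The remaining 4 lists were not called and had no member past either threshold. Targets of p53 had a median of -0.08 (adjusted p = 0.739), with Cdkn1a at -0.21 (SE 0.07) and Xpc at 0.30 (SE 0.12). Interferon response genes gave -0.11 (adjusted p = 0.907), with Stat2 at 0.24 (SE 0.20) and Dhx58 at 0.28 (SE 0.27). Nerve and synapse genes gave -0.11 (adjusted p = 0.281), with Grin1 at 0.25 (SE 0.07) and Gap43 at -0.40 (SE 0.12). Targets of NRF2, the regulator of the oxidative stress response, gave 0.03 (adjusted p = 0.907), with Abcc1 at 0.32 (SE 0.09) and Nqo1 at -0.35 (SE 0.12). The median, the mean and the camera direction differed in sign for the lists of other islet cells (median -0.07, mean 0.02, direction up), 40S ribosomal proteins (median 0.01, mean -0.04, direction up), cytosolic chaperones (median 0.00, mean -0.02, direction down) and 60S ribosomal proteins (median -0.02, mean -0.03, direction up).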

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

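The thinned and trend-removed settings, the latter also with an estimated correlation, were chosen after the data were seen. The count of 23 genes stayed within 1.5 times with DESeq2 size factors, upper-quartile factors, at least 1 CPM in 3 libraries, a mean of at least 50 counts, genes above 1% left out, protein-coding genes only, thinning and trend removal (17 to 26 genes). It was 227 with DESeq2 (183 higher, 44 lower; 11 shared with the 23), 40 with limma-voom (19 higher, 21 lower; all 23 shared), 42 with total counts, which moved the median of all genes by -0.08 (8 higher, 34 lower, against 11 and 12; the split was 7 and 13 with the trend removed), 222 with no filter on low counts, 7 at an adjusted p of 0.01, 119 at 0.1 (70 higher, 49 lower) and 8 against a fold of 1.2. Fewer genes pass a stricter threshold or a fold minimum by construction. The cause of the other shifts was not tested. Leaving out one library gave 4 to 333 genes: 9 without sgNT library 1 or 2, 12 without sgNT library 3, 6 without sgLTN1 library 1, 4 without sgLTN1 library 2 and 333 without sgLTN1 library 3, which held all 23. Ltn1 and Ass1 passed in every setting that gave an adjusted p (19 and 18), as did Dcpp2 and Dcpp3 (17), and every one of the 23 genes kept its direction. The Ltn1 fold change ran from -1.06 to -1.17. Rnf10 stayed negative, from -0.26 to -0.42, and passed in no setting.

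Whether library numbers pair the samples was not settled. Deviations from the group mean correlated at -0.05, 0.07 and 0.09 between same-numbered libraries, and 3 of 6 libraries correlated best with their own number. These few values show no clear pairing but cannot exclude it. The fit with the replicate number as a block gave 609 genes (406 higher, 203 lower), 23 of them shared, and 13 lists. It left Rnf10 at -0.33 (adjusted p = 0.0821). The standard error of Ltn1 was 0.057 in the blocked fit and 0.068 in the main one, so pairing by number stays open.

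The count of 13 lists became 0 with an estimated correlation, with the trend kept or removed, and 0 with one-way fry, was 19 with fry in either direction, and stayed between 9 and 14 in the other settings (14 with the trend removed, 2 of them up and 12 down; 9 to 12 when one library was left out). Among values that changed sign, with the cause not tested, were Ins2 (-0.15), Ins1 (-0.0856), Spp1 (-0.0336), the secretory granule list (-0.0305) and the lysosome list (-0.0240) with the trend removed, and the log2 fold change of Rps3 with upper-quartile factors (-0.0107), total counts (-0.0653), the trend removed (-0.0590) and between -0.0143 and 0.0471 when one library was left out, negative without sgNT library 1 or sgLTN1 library 3. None of these single genes was called in either direction. With the trend removed the medians of lists not called before also crossed 0 for cytosolic chaperones (to -0.0970), 40S ribosomal proteins (to -0.0266) and the interferon response (to 0.00283), and medians of other uncalled lists crossed 0 when a library was left out. The differences in share between the guides, in percentage points, depended on which library was left out. For Ins1 and Ins2 and for the 10 most abundant genes, the order of the shares by depth is given above. For Ins1 and Ins2 the value of 0.0581 became -0.0678 without sgNT library 2, -0.268 without sgLTN1 library 3 and 0.389 without sgLTN1 library 1, and for the 10 most abundant genes 0.0549 became -0.417, -0.649 and 0.687. The mitochondrial value of -0.109 ran from -0.171 without sgNT library 2 to -0.0386 without sgNT library 3, and the ribosomal protein value of -0.0206 from -0.0393 without sgNT library 1 to -0.00871 without sgNT library 3.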

Other observations

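The tests of depth and of shared reads for the Dcpp genes, and of the abundance trend as the whole cause of the ER pattern, were chosen after the result was seen, and the patterns themselves were noticed in these data. Beyond the fixed lists, membrane and extracellular protein families defined by symbol, such as solute carriers, channels, laminins and adhesion receptors, had a median log2 fold change of 0.11, with 504 of 748 genes above 0, whereas families made in the cytosol had -0.05, with 748 of 1223 genes below 0. Core replication-dependent histone genes had a median of -0.22, with 48 of 60 below 0. With the abundance trend removed their median was -0.26, but the library deviations in that setting overlapped between the groups (sgNT -0.01, 0.11 and 0.23, sgLTN1 -0.13, -0.21 and 0.00). The 5 linker histone genes H1f1 to H1f5 all lay below 0 with a median of -0.36 with the trend kept. Copies within these histone families share sequence, so counts of single members are uncertain.

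The abundant transcripts were those of an endocrine cell, with Ins2, Chga and Iapp at the top. Lars2, a mitochondrial tRNA synthetase gene, held rank 4 with 2.60% ± 0.459 of the counts in sgNT and 2.25% ± 0.492 in sgLTN1 (two-sided exact permutation p = 0.3). Its share went with depth. It was 2.82%, 2.91% and 2.80% in sgNT 1, sgNT 3 and sgLTN1 3, the libraries of smallest total, and 2.07%, 1.86% and 2.09% in sgNT 2, sgLTN1 1 and sgLTN1 2. Whether all of these reads come from translated Lars2 mRNA was not tested. On the first principal component of the log CPM values (30.6% of variance) sgLTN1 libraries 1 and 2 (18.7 and 19.6) and sgNT library 3 (-26.5) lay at opposite ends. On component 2 (24.1%) sgNT library 1 (28.5) lay opposite sgNT library 3 (-15.7), and on component 3 (22.2%) sgLTN1 library 3 lay apart (29.8).

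The higher footprints on ER unfolded protein response genes in sgLTN1 were weighed first. The median was 0.17 with all libraries thinned to the smallest total, which argues only against unequal counting precision. Random thinning keeps the proportions within each library, so it cannot exclude a bias tied to depth. The abundance trend could account for part, as the median fell from 0.16 to 0.06 (0.05996) without it, 36.5% of its size. As the whole cause it was argued against at the preset correlation only: the 95% bootstrap interval of that median, which treats genes as independent, ran from 0.0134 to 0.0969, while the adjusted p with an estimated correlation was 0.415. A candidate explanation is a higher share of footprints from many mRNAs translated at the ER. Without the trend, membrane and extracellular families outside the lists lay 0.14 (0.137451) above cytosol-made ones (95% bootstrap interval 0.12 to 0.16). This class score was -0.04, -0.07 and -0.08 in the sgNT and 0.06, 0.10 and 0.04 in the sgLTN1 libraries (exact permutation p = 0.1, the smallest possible). The membrane and extracellular families alone had a median of 0.0993 without the trend (95% bootstrap interval 0.0839 to 0.115). The ER list, at 0.06, did not exceed them. The medians of the secretory granule and lysosome lists did not share the class shift once the trend was removed. These lists mix products that pass through the ER with products made in the cytosol, such as those of Rab3a and Sqstm1. Their medians were 0.11 and 0.11 with the trend kept and -0.0305 and -0.0240 with it removed. Abundance does not set the lysosome list apart, as its median log2 CPM was 8.19 against 8.17 for the ER list (secretory granule 9.10). Medians of such mixed lists cannot decide whether the candidate explanation extends to their members that pass through the ER. Recovery of ER-bound ribosomes during lysis was not tested, and an effect of the Ltn1 guide on the unfolded protein response itself stays open.

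The near absence of Dcpp1, Dcpp2 and Dcpp3 footprints in sgLTN1 was weighed next. Lower depth was argued against by the totals alone, as sgLTN1 was the deeper group (25875181 against 16655511 counts), and 315 counts at the sgNT rate against 1 seen only restates the fall. The summed counts of 203 and 1 (upper 95% limit of the sgLTN1 to sgNT ratio 0.0179) likewise follow from the 3 single counts, and show only that no member of the trio held the reads missing from the others. Loss of a wider chromosomal segment cannot be told apart from a change of these genes alone: of 10 neighbouring genes only Elob was tested, at -0.15 (SE 0.08), and the other 9 held 27 counts in sgNT and 34 in the deeper sgLTN1 group, too few to test. Silencing of the cluster or descent of the sgLTN1 cells from few founders may be considered as hypotheses, and neither was tested.

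The lower linker histone footprints were weighed last. A shift of cytosol-made families as a class was argued against, since their median of -0.04 (-0.0381) without the trend did not reach -0.22, the bound set for this explanation against the linker histone median of -0.43. Fewer cells in S phase may contribute: without the trend, 15 S-phase genes such as Pcna and Mcm3 had a median of -0.15 (95% bootstrap interval -0.22 to -0.07), against -0.09 with the trend kept (12 of 15 below 0), and core histones, with the overlap given above, -0.26. The S-phase genes belong to the cell cycle list reported above, so they are not independent of it. Growth state of the cultures and an effect of the Ltn1 guide on proliferation stay open as untested explanations.

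With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split gave 23 genes and the highest other split 13 (sgNT 1, sgNT 3 and sgLTN1 3 against the rest). That other split sets the 3 libraries with the smallest totals (4373467, 4479680 and 4993245 counts) against the 3 deepest. Depth is therefore the strongest competing grouping for the gene count. The real split gave 13 lists and the highest other split 11 (sgNT 2, sgNT 3 and sgLTN1 3 against the rest). In both cases 1 split, the real one, reached the real value.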
